A study of Saccharomyces cerevisiae with 12 samples.

How the data were processed

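RNA was measured in 12 libraries of haploid budding yeast labelled W303-1B, 3 per group (WT, mfb1, aac2mut and mfb1_aac2mut). Per the labels' protocols, cells grew at 25 °C in medium with 1% yeast extract, 2% peptone, 2% glycerol and 2% ethanol to an optical density of about 1 to 2, total RNA was extracted with glass beads and phenol, and libraries were made with a stranded Illumina mRNA kit. Per the submitters' processing notes, the tools were bcl2fastq, cutadapt 1.2.1 and Bowtie2, and the genome build was sacCer3. The counting program, its strand setting and the annotation are not given in the sources used here, so a gene and an overlapping or antisense neighbour cannot be told apart. Groups and replicate numbers were taken from the sample titles.

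The deposited table holds log2 values, normalized by the authors, for 6672 features in the 12 libraries, with no value column left out. What was done was read from the values. The highest value was 18.15 in each library, and the sorted values of the libraries differed by a median of 0.0019 (0.173 at most) above the count minimum used here. The values turned back to the linear scale had the same sum in each library, to 4 digits. The table thus has the form of log2(count + 1) after quantile normalization across libraries. It gives every library the same distribution, so that a change in total mRNA or in the shape of the distribution is removed, and the reads per gene and the depth per library cannot be recovered. Values near 0 rest on few reads, and 160 to 252 features per library were listed at 0. No confidence interval from counts is given. The precision comes from the spread between the 3 libraries of a group.

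The plan, written before the data were examined, was limma on log2(value + 1) of linear normalized counts. As the deposited values are already on that scale, limma was run on them as deposited, and models for whole reads could not be run. Features with at least 10 on the linear scale (2 to the power of the value, minus 1) in at least 3 libraries were kept, which left 6044. A linear model with 1 mean per group was fitted to all 12 libraries with limma 3.58.1 (R 4.3.3, lmFit and eBayes with trend = TRUE), with 8 residual and 5.06 prior degrees of freedom. The moderated tests were two-sided with Benjamini-Hochberg adjustment, and a feature was called at an adjusted p under 0.05. A log2 fold change is a difference of group means with its standard error, and fold changes of low genes are understated by the offset of 1. The 5 comparisons were aac2mut with WT, mfb1_aac2mut with mfb1, mfb1 with WT, mfb1_aac2mut with aac2mut, and the interaction, (mfb1_aac2mut - mfb1) - (aac2mut - WT).

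Gene lists (37, with 1186 genes, 1171 of them tested) were fixed before the data were examined, from textbook knowledge of import stress, respiratory growth and strain and cell type markers. Lists with at least 5 tested genes (35) were tested with camera (correlation 0.01, Benjamini-Hochberg over the lists of a comparison) and again with an estimated correlation. Genes encoded in mitochondrial DNA were not analysed here. Names and coordinates came from the R64 annotation, the assembly from which sacCer3 derives. Of the features, 5849 matched by symbol, 188 by locus tag and 9 by a synonym, and 626 did not match.

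The genes named were MFB1, PET9 and HSP31 and, in each comparison, the 8 largest rises and 8 largest falls among called genes with a mean of at least 50 on the linear scale in the higher group and no overlap between the 3 libraries of one group and the 3 of the other. From each list that was called, or had at least 3 called members, up to 4 genes with the smallest adjusted p could be named. Selection markers were kept apart, and LYS2 and CIS1 were added after their values were seen, as were the genes of families named with the further observations. Of the genes that the rule names in the interaction through a list, those printed were narrowed, after their values were seen, to ones that kept their call without each library in turn. Pearson and Spearman correlations of effects are across genes and carry no p.

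Replicates of a group correlated with r between 0.989 and 0.996 and differed by a median of 0.063 to 0.136, and no 2 libraries were identical. The fit was tested on simulated libraries with known changes in some genes. For aac2mut versus WT (5992 genes) it recovered 74.6% of changes of 0.5, 91% of changes of 1 and 98.5% of changes of 2 on the log2 scale, and 8.33% of the calls were false. For the interaction (5989 genes) the shares were 50.7%, 88.1% and 95.5%, and 5.45% of the calls were false. Few genes were changed in the simulation and the noise was independent between genes, unlike in the libraries here. These shares therefore need not hold for the real comparisons. The alternatives were other pseudocounts (0.1 and 5), no filter or a filter of 50, recomputed TMM and median-ratio factors, quantile normalization, limma without trend or with robust empirical Bayes, the replicate number as a block, only the libraries compared, a limit of 2-fold, and each library left out in turn. Added after seeing the data were protein-coding genes only, no mating-type genes, no genes of chromosome V and the share of ribosomal RNA features as a covariate.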

Results

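Transcript levels were measured in 12 RNA-seq libraries of budding yeast, 3 for each of 4 strains that form a 2 by 2 design. The strains, all labelled haploid W303-1B, carried the MFB1 gene or a deletion of it, with or without an added allele of the mitochondrial ADP/ATP carrier, aac2(A128P,A137D). Mfb1 is an F-box protein of mitochondria, and the mutant carrier is known to clog the import channels that bring proteins into the organelle. The groups are named WT, mfb1 (the deletion), aac2mut (the clogging allele) and mfb1_aac2mut (both). Cultures grew at 25 °C on glycerol and ethanol, carbon sources that have to be respired. The title of the series asks whether Mfb1 and Hsp31, the yeast homolog of human DJ-1, are needed under import clogging. The deposited values were log2 normalized counts for 6672 features, of which 6044 were tested. Sequencing depth is unknown. The labels do not say whether the 3 libraries of a group came from separate cultures, so p-values measure only the spread between these libraries.

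The targeted gene followed the labels in all 12 libraries. MFB1 (YDR219C, protein-coding, chromosome IV, 905455 to 906852 in R64) stood at 11.29 ± 0.10 in WT and 11.06 ± 0.12 in aac2mut (log2 values, SD, n = 3). It was listed at 0 to 1.15 in the mfb1 libraries and at 0 to 1.05 in the mfb1_aac2mut libraries. PET9, the standard name of AAC2 (YBL030C, chromosome II, 163041 to 163997), was higher wherever the clogging allele was present. It rose from 14.83 ± 0.08 in WT to 16.50 ± 0.07 in aac2mut, and from 14.71 ± 0.02 in mfb1 to 15.89 ± 0.05 in mfb1_aac2mut, and the counts take in reads of both alleles. HSP31 (YDR533C, chromosome IV, 1501447 to 1502160) stood at 12.68 ± 0.07 in WT, 12.79 ± 0.12 in mfb1, 11.05 ± 0.12 in aac2mut and 12.03 ± 0.27 in mfb1_aac2mut. LYS2, a lysine biosynthesis gene that also serves as a selection locus (YBR115C, chromosome II, 469748 to 473926), was present without the clogging allele, at 10.91 ± 0.15 in WT and 10.57 ± 0.07 in mfb1. LYS2 was listed at 0 in all 3 aac2mut libraries and at 0 to 1.59 in mfb1_aac2mut. The genotype labels do not mention it. The groups with and without the clogging allele therefore differed in the allele and in LYS2 expression alike, in both comparisons that cross the allele and in the interaction, and no library separates these differences.

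**Figure D1:**
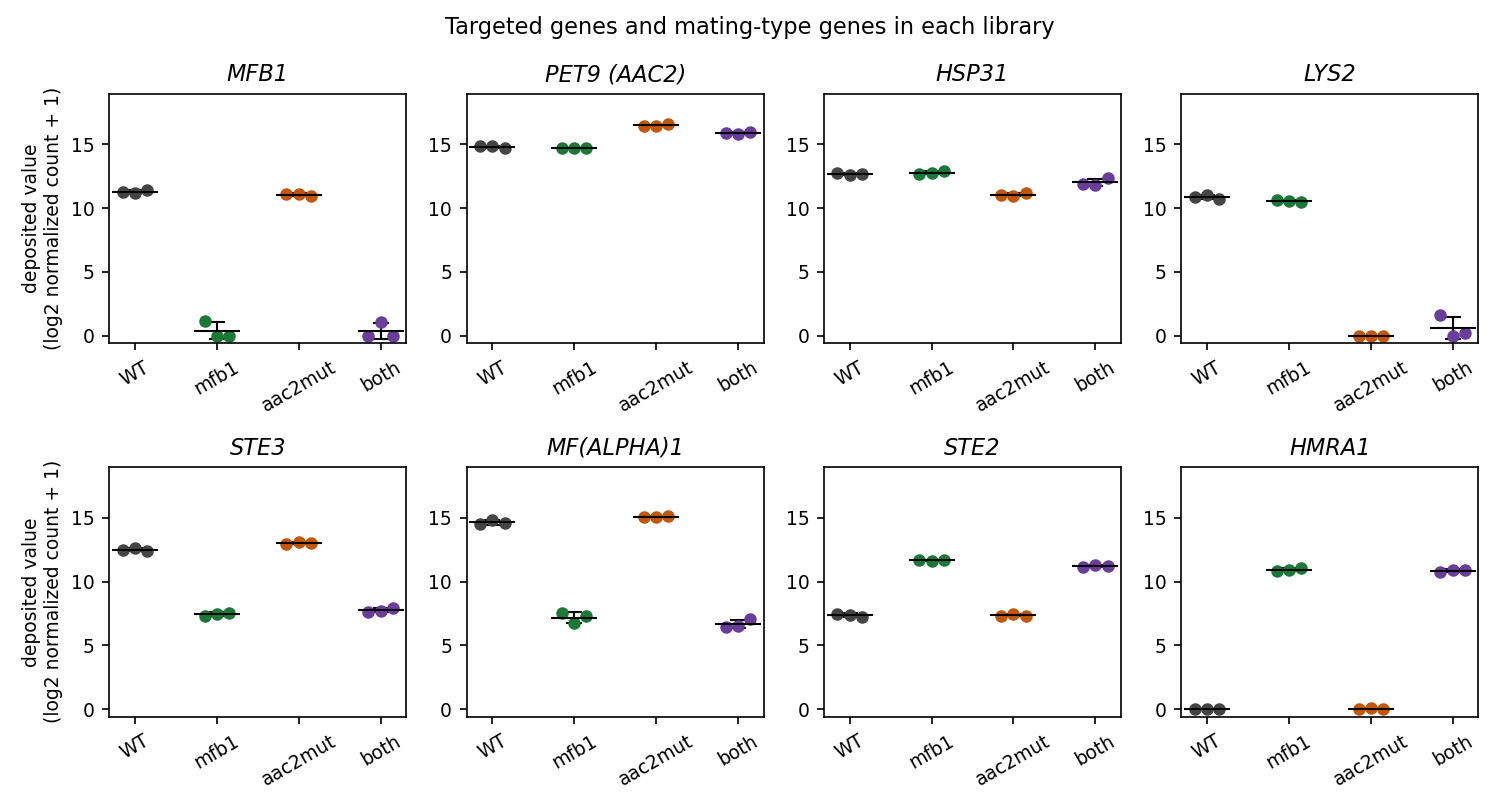
Each point is a library, the bar its group mean and the whiskers the SD (n = 3), on the scale of the deposited log2 values. MFB1 is near 0 in both deletion groups, LYS2 is near 0 in both groups with the clogging allele, and the mating-type genes STE3, MF(ALPHA)1, STE2 and HMRA1 divide the libraries as MFB1 does ("both" is mfb1_aac2mut).

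Mating-type genes split the libraries along the same line as MFB1. W303-1B is a MATα strain, and the MFB1 libraries expressed MATα genes. STE3, the a-factor receptor, stood at 12.51 ± 0.11 in WT and 13.04 ± 0.07 in aac2mut, against 7.45 ± 0.15 in mfb1 and 7.76 ± 0.14 in mfb1_aac2mut. All 9 genes of the list of MATα genes were lower in both deletion groups than in the matching MFB1 groups, and all 7 MATa genes were higher. STE2, the α-factor receptor of MATa cells, stood at 7.36 ± 0.15 in WT and 7.36 ± 0.09 in aac2mut, against 11.68 ± 0.04 in mfb1 and 11.23 ± 0.08 in mfb1_aac2mut. HMRA1, which has the same sequence as the MATa1 gene, was listed at 0 in WT and stood at 10.96 ± 0.10 in mfb1. Reads of the silent and active mating-type copies cannot be told apart, so the 4 alpha genes of HML and MAT are uncertain. The deletion libraries therefore differed from the others both in MFB1 and in the expression of mating-type genes. This holds in every comparison that crosses the deletion and in the interaction.

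The aac2mut and WT libraries compare cells that have MFB1 with and without the clogging allele, together with the difference in LYS2 expression. The effect of the clogging allele stands for this difference between strains. Of the 6044 features, 1295 were higher and 1195 lower in aac2mut (limma, Benjamini-Hochberg adjusted p under 0.05), and 145 of these moved at least 2-fold. General stress genes fell. Of the 44 tested targets of the stress factors Msn2 and Msn4, 35 fell and 0 rose (36 and 0 adjusted over the list alone), with a median of -0.77 on the log2 scale (camera adjusted p = 3.04e-17, and adjusted p = 0.0579 with an estimated correlation). Among them SOL4 changed by -1.66 ± 0.10 (SE), RTC3 by -1.38 ± 0.08 and STF2 by -1.03 ± 0.07, each with an adjusted p of at most 5.05e-07. Genes for trehalose and glycogen, the storage carbohydrates, fell in 15 of 20 cases (15 adjusted over the list alone, median -0.52, adjusted p = 4.71e-07, adjusted p = 0.303 with an estimated correlation), with PGM2 at -1.07 ± 0.13 and UGP1 at -0.78 ± 0.09. Of 33 cytosolic chaperone genes linked to the heat shock factor Hsf1, 22 fell and 4 rose (22 and 4 adjusted over the list alone, median -0.41, adjusted p = 6.98e-07, adjusted p = 0.303 with an estimated correlation). The Hsp70 gene SSA4 changed by -2.11 ± 0.18 and the small heat shock genes HSP26 and HSP42 by -1.67 ± 0.12 and -1.22 ± 0.10. The share of ribosomal RNA features in the values was 2.00 ± 0.27% in WT and 1.32 ± 0.10% in aac2mut (SD, n = 3).

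HSP31 was among the genes that fell in aac2mut, by 1.63 on the log2 scale (SE 0.11, 3.1-fold, adjusted p = 5.2e-07), with all 3 aac2mut libraries below all 3 WT libraries. In the list of the Hsp31 family and of enzymes that remove methylglyoxal, 8 of 11 genes fell and 0 rose (9 and 0 adjusted over the list alone, median -0.48, adjusted p = 9.99e-05, adjusted p = 0.303 with an estimated correlation). They included the glyoxalase GLO1 at -0.59 ± 0.06 and the aldose reductase GRE3 at -0.67 ± 0.07. HSP32, HSP33 and SNO4, the other members of the family, are near-identical to each other, and their values are uncertain. Oxidative stress genes, most of them under Yap1, fell in 23 of 39 cases and rose in 3 (25 and 3 adjusted over the list alone, median -0.37, adjusted p = 4.77e-08, adjusted p = 0.0557 with an estimated correlation). The NADPH dehydrogenases OYE3 and OYE2 changed by -1.96 ± 0.09 and -1.49 ± 0.08, and the glutathione transferase GTT2 by -1.05 ± 0.07. Proteasome genes fell in 20 of 44 cases and rose in 1 (21 and 1 adjusted over the list alone), by little each (median -0.16, adjusted p = 6.21e-05, adjusted p = 0.303 with an estimated correlation). Autophagy genes fell in 14 of 33 cases and rose in 2 (14 and 3 adjusted over the list alone, median -0.19, adjusted p = 0.00754, adjusted p = 0.364 with an estimated correlation).

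Genes of iron uptake and several lists of mitochondrial genes had positive medians in aac2mut against WT, but not the list of the respiratory complexes. Of 30 iron regulon genes, 21 rose and 2 fell (21 and 2 adjusted over the list alone), with a median of 0.55. This was the only one of the 17 lists called in this comparison that kept its call with an estimated correlation (adjusted p = 4.77e-08 and adjusted p = 0.0246). The siderophore transporter SIT1 rose by 1.87 ± 0.10, the high-affinity iron permease FTR1 by 1.33 ± 0.09 and its oxidase FET3 by 1.21 ± 0.10. Of 75 genes of the mitochondrial ribosome, 63 rose and 2 fell (67 and 2 adjusted over the list alone, median 0.32, adjusted p = 3.04e-17, adjusted p = 0.303 with an estimated correlation), with MRP4 at 0.63 ± 0.05. Import machinery rose in 22 of 42 cases and fell in 2 (23 and 2 adjusted over the list alone, median 0.21, adjusted p = 5.23e-05, adjusted p = 0.303 with an estimated correlation). TIM23, the channel of the inner membrane, rose by 0.58 ± 0.05, and TOM40, the channel of the outer membrane, by 0.44 ± 0.05. Mitochondrial chaperones and proteases rose in 14 of 28 cases and fell in 2 (14 and 3 adjusted over the list alone, median 0.18, adjusted p = 0.000837, adjusted p = 0.303 with an estimated correlation), among them both subunits of the m-AAA protease, AFG3 at 0.62 ± 0.05 and YTA12 at 0.58 ± 0.05. Of 17 genes of the tricarboxylic acid cycle, 14 rose and 0 fell (14 and 0 adjusted over the list alone, median 0.30, adjusted p = 0.000255, adjusted p = 0.364 with an estimated correlation). Nuclear genes of the respiratory complexes went both ways, with 12 of 44 higher and 9 lower (12 and 9 adjusted over the list alone, median -0.01, adjusted p = 0.954). CIS1, known from an import stress response that Pdr3 directs, was measured at 0.28 ± 0.16 (adjusted p = 0.175).

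Outside mitochondria, ribosome biogenesis genes rose in 46 of 100 cases and fell in 0 (50 and 0 adjusted over the list alone, median 0.27, adjusted p = 4.77e-08, adjusted p = 0.516 with an estimated correlation), whereas the 132 proteins of the cytosolic ribosome had a median of 0.01 with 5 higher and 0 lower (0 and 0 adjusted over the list alone, adjusted p = 0.776). Ergosterol synthesis genes rose in 19 of 30 cases and fell in 0 (20 and 0 adjusted over the list alone, median 0.24, adjusted p = 4.39e-05, adjusted p = 0.325 with an estimated correlation), with ERG3 at 0.95 ± 0.12. The largest rises also took in the hexose transporters HXT1 (2.05 ± 0.21) and HXT2 (1.75 ± 0.14), PET9 (1.67 ± 0.06), the transporter VBA5 (1.80 ± 0.23), ECM13 (1.69 ± 0.18) and SYG1 (1.60 ± 0.11). YIL047C-A, which adjoins SYG1, rose by 2.10 ± 0.24. The largest falls also took in ANB1, an eIF5A gene of cells short of oxygen (-2.57 ± 0.25), HXT13 (-2.02 ± 0.30) and the aldehyde dehydrogenase ALD3 (-1.89 ± 0.16). YPR137C-A (-5.69 ± 1.43) and YLR227W-A (-2.03 ± 0.58) are Gag genes of Ty elements and YLR154W-E (-3.46 ± 0.62) lies among the ribosomal DNA repeats, so these counts are uncertain, and YLR227W-A was not called without WT replicate 1 (adjusted p = 0.0566). The selection marker LEU2 was lower by 1.11 on the log2 scale in aac2mut. Of 15 tested strain markers 5 were lower and 2 higher (camera adjusted p = 0.062). They were read apart from the other genes because strain markers differ between strains.

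The mfb1_aac2mut and mfb1 libraries compare cells without MFB1 with and without the clogging allele, again together with the difference in LYS2 expression. Here 1010 features were higher and 1055 lower, and 108 of these moved at least 2-fold. Iron regulon genes rose in 21 of 30 cases and fell in 2 (21 and 2 adjusted over the list alone, median 0.48), the only one of 21 called lists that kept its call with an estimated correlation (adjusted p = 2.86e-07 and adjusted p = 0.0348). SIT1 rose by 1.44 ± 0.10 and FTR1 by 0.77 ± 0.09. Mitochondrial chaperones and proteases rose in 18 of 28 cases and fell in 0 (19 and 0 adjusted over the list alone, median 0.22, adjusted p = 2.86e-07, adjusted p = 0.205 with an estimated correlation), with AFG3 at 0.82 ± 0.05, YTA12 at 0.73 ± 0.05 and the matrix Hsp70 gene SSC1 at 0.66 ± 0.09. The mitochondrial ribosome rose in 42 of 75 cases and fell in 1 (46 and 1 adjusted over the list alone, median 0.21, adjusted p = 2.65e-12, adjusted p = 0.419 with an estimated correlation). In a drug resistance list built around Pdr1 and Pdr3, 12 of 26 genes rose and 1 fell (13 and 2 adjusted over the list alone, median 0.27, adjusted p = 0.000656, adjusted p = 0.32 with an estimated correlation). Some members, PDR12 among them, are not known as targets of these factors. The transporter genes PDR12 and PDR10 rose by 1.41 ± 0.18 and 1.11 ± 0.12. CIS1 of the same list was measured at -0.02 ± 0.16 (adjusted p = 0.928).

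Genes of the cytosolic ribosome fell in mfb1_aac2mut against mfb1 in 74 of 132 cases and rose in 0 (84 and 0 adjusted over the list alone, median -0.29, adjusted p = 1.3e-14, adjusted p = 0.519 with an estimated correlation), with RPS27A at -0.76 ± 0.12 and RPL33A at -0.49 ± 0.08. Histone and cell cycle genes fell in 22 of 35 cases and rose in 0 (24 and 0 adjusted over the list alone, median -0.29, adjusted p = 2.49e-08, adjusted p = 0.21 with an estimated correlation). Those with the smallest p, DSE1 (-1.08 ± 0.09), SCW11 (-1.08 ± 0.11) and CTS1 (-0.81 ± 0.09), are known to act when daughter cells separate. Targets of Msn2 and Msn4 fell in 20 of 44 cases and rose in 5 (21 and 6 adjusted over the list alone, median -0.28, adjusted p = 0.00166, adjusted p = 0.419 with an estimated correlation). HSP31 fell by 0.76 on the log2 scale (SE 0.11, adjusted p = 0.000264). Among the largest rises were HXT15 (2.26 ± 0.23), whose reads are shared with the near-identical HXT16, VBA5 (1.78 ± 0.23), HXT2 (1.67 ± 0.14), HXT1 (1.66 ± 0.21), the pyridoxine synthesis gene SNO1 (1.54 ± 0.14), SYG1 (1.52 ± 0.11), YIL047C-A (1.99 ± 0.24) and YAR066W (1.87 ± 0.38). Among the largest falls were ANB1 (-1.92 ± 0.25), RPL41B (-1.48 ± 0.33), YNL277W-A (-1.58 ± 0.22) and YDR034W-B (-1.93 ± 0.30). YGL123C-A (-2.24 ± 0.44), YCR013C (-1.97 ± 0.47), BUD19 (-1.93 ± 0.46) and YKL153W (-1.90 ± 0.53) overlap highly expressed genes and are uncertain, and YKL153W was not called without mfb1_aac2mut replicate 1 or without mfb1_aac2mut replicate 2 (adjusted p up to 0.0633). The share of ribosomal RNA features was 2.91 ± 1.24% in mfb1 and 3.53 ± 1.26% in mfb1_aac2mut.

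The effects of the clogging allele with and without MFB1 went together across genes, with a Pearson r of 0.56 and a Spearman rho of 0.50 over the 6044 features, which are not independent replicates. These 2 comparisons share no library. Of the genes called, 643 were higher in both against 216.4 for independent lists, and 510 were lower in both against 208.6, while 56 were called in opposite directions.

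The interaction asks whether the effect of the clogging allele differed between cells with and without MFB1. It differed for 639 features (332 positive, 307 negative), of which 50 by at least 2-fold. Targets of Msn2 and Msn4 had a positive interaction in 23 of 44 cases and a negative one in 0 (35 and 1 adjusted over the list alone, median 0.53, adjusted p = 5.68e-16, adjusted p = 0.227 with an estimated correlation). Trehalose and glycogen genes did so in 10 of 20 cases, with 0 negative (18 and 0 adjusted over the list alone, median 0.54, adjusted p = 6.9e-10, adjusted p = 0.337 with an estimated correlation), and Hsf1-linked chaperones in 11 of 33, with 0 negative (15 and 4 adjusted over the list alone, median 0.24, adjusted p = 0.000105, adjusted p = 0.337 with an estimated correlation). SSA4, for example, stood at 14.82 in WT, 12.71 in aac2mut, 14.61 in mfb1 and 14.07 in mfb1_aac2mut, a difference of the 2 effects of 1.57 ± 0.26 (adjusted p = 0.0053). HSP30, a membrane heat shock gene, had a difference of 1.36 ± 0.13 (adjusted p = 0.000656), OYE3 of 1.15 ± 0.13 (adjusted p = 0.00171) and HSP26 of 1.29 ± 0.17 (adjusted p = 0.00251). The fall of HSP31 was smaller without MFB1 by 0.87 ± 0.16 (adjusted p = 0.00782), and the rise of PET9 was smaller by 0.48 ± 0.09 (adjusted p = 0.00828).

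Ribosome biogenesis genes had a negative interaction in 28 of 100 cases and a positive one in 0 (56 and 0 adjusted over the list alone, median -0.47, adjusted p = 1.69e-18, adjusted p = 0.337 with an estimated correlation). The snoRNP methyltransferase NOP1 rose from 12.35 to 12.72 with the clogging allele in cells with MFB1 and went from 12.23 to 11.89 without it (difference -0.71 ± 0.12). Cytosolic ribosome genes had a negative interaction in 15 of 132 cases and a positive one in 0 (40 and 0 adjusted over the list alone, median -0.31, adjusted p = 2.07e-17, adjusted p = 0.39 with an estimated correlation), and histone and cell cycle genes in 7 of 35, with 0 positive (11 and 0 adjusted over the list alone, median -0.31, adjusted p = 8.24e-07, adjusted p = 0.337 with an estimated correlation). The largest negative values included the cell cycle repressors YHP1 (-1.55 ± 0.26) and YOX1 (-1.54 ± 0.27), the phosphate transporter PHO84 (-1.45 ± 0.19), ECM13 (-1.28 ± 0.25) and the cyclin PCL1 (-1.18 ± 0.23). Of the 35 lists tested, 16 were called with the preset correlation and 0 with an estimated one, and 1797 features had an unadjusted p under 0.05. The count of 639 depended on single libraries, falling to 200 without WT replicate 3, 288 without mfb1_aac2mut replicate 1, 318 without mfb1 replicate 3, 345 without WT replicate 1, 363 without aac2mut replicate 3 and 369 without aac2mut replicate 1, and rising to 966 without WT replicate 2. With the share of ribosomal RNA features as a covariate, an alternative chosen after seeing the data, it was 372.

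**Figure D2:**
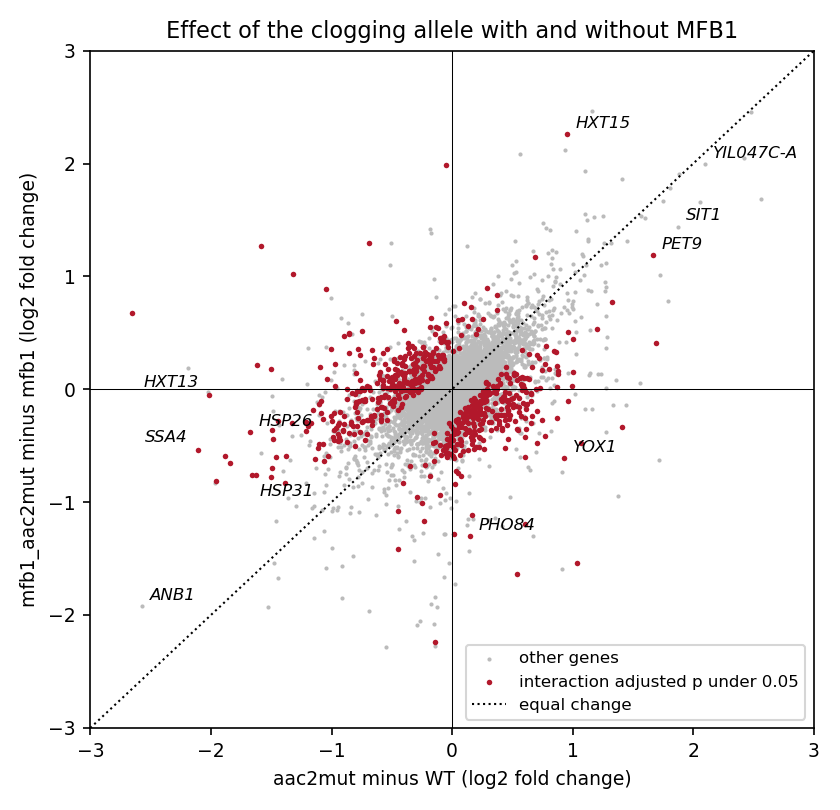
Each point is a gene, with the log2 fold change of the clogging allele in cells with MFB1 (x axis) and without MFB1 (y axis). The dotted line marks equal change, red points have an interaction adjusted p under 0.05, and 6 genes lie outside the axes at 3. HSP31, HSP26 and SSA4 fell further with MFB1 than without it, and SIT1 and PET9 rose in both.

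The mfb1 and WT libraries show the deletion in cells without the clogging allele. Apart from the mating-type genes the differences were small. Of 400 features called, 233 were higher and 167 lower, 25 were mating-type genes or their neighbours, and of the other 375 only 10 differed at least 2-fold. The 16 features with the largest changes were the deleted gene, mating-type genes or their neighbours, and CHA1, the serine and threonine deaminase (1.64 ± 0.18, adjusted p = 0.000126). CHA1 lies close to HML on chromosome III, so its change cannot be read apart from the mating-type loci. AGA2 rose by 5.05 ± 0.24, STE2 by 4.33 ± 0.09, ASG7 by 3.93 ± 0.30, BAR1 by 3.34 ± 0.10 and YLR041W, next to AFB1, by 2.17 ± 0.33. STE3 changed by -5.06 ± 0.09, AFB1 by -3.57 ± 0.10 and SAG1 by -3.25 ± 0.11. MF(ALPHA)1 stood at 14.65 ± 0.18 in WT and 7.18 ± 0.41 in mfb1, MF(ALPHA)2 at 10.79 ± 0.01 and 1.10 ± 0.97, and MFA2 at 0.51 ± 0.88 and 6.42 ± 0.32. The 2 mating-type lists were called, also with an estimated correlation (adjusted p = 0.000757 for MATα and adjusted p = 0.000828 for MATa genes). In both lists all genes passed, over all features and adjusted over the list alone. Genes expressed in haploid cells of either mating type hardly moved as a list, with 0 of 19 higher and 2 lower (3 and 4 adjusted over the list alone, median -0.03, adjusted p = 0.381), and 0 of 26 meiosis genes changed (0 adjusted over the list alone, adjusted p = 0.773).

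Nuclear genes of the respiratory complexes were slightly higher in mfb1 than in WT, in 11 of 44 cases with 0 lower (25 and 0 adjusted over the list alone, median 0.19, adjusted p = 7.8e-10, adjusted p = 0.358 with an estimated correlation). In the list of the Hsp31 family and methylglyoxal enzymes, 4 of 11 genes rose and 0 fell (6 and 0 adjusted over the list alone, median 0.23, adjusted p = 3.56e-05, adjusted p = 0.358 with an estimated correlation), with the reductase YPR1 at 0.40 ± 0.05. HSP31 itself was measured at 0.11 ± 0.11 (adjusted p = 0.61) and PET9 at -0.13 ± 0.06 (adjusted p = 0.264). Of the oxidative stress genes, 11 of 39 rose and 3 fell (16 and 3 adjusted over the list alone, median 0.15, adjusted p = 0.00416, adjusted p = 0.358 with an estimated correlation), among them the mitochondrial superoxide dismutase SOD2 at 0.43 ± 0.06. Medians of the other called lists went both ways. The tricarboxylic acid cycle stood at 0.12 (camera adjusted p = 0.00806) and import machinery at 0.095 (camera adjusted p = 0.0461). Ribosome biogenesis stood at -0.13 (camera adjusted p = 5.48e-06) and sulfur and methionine genes at -0.21 (camera adjusted p = 4.63e-05). Trehalose and glycogen genes stood at -0.16 (camera adjusted p = 0.000451) and Hsf1-linked chaperones at -0.17 (camera adjusted p = 0.00416). Each of these had an adjusted p of 0.591 with an estimated correlation. The count of 400 fell to 163 without mfb1 replicate 1, 170 without WT replicate 1, 201 without mfb1 replicate 3 and 220 without WT replicate 3, to 260 with only the 6 libraries compared and to 148 with the share of ribosomal RNA features as a covariate, which was 4.33% in mfb1 replicate 1 against 2.02% and 2.38% in the other mfb1 libraries. The covariate was chosen after seeing the data. Of the genes called, 58.3% were higher without it and 39.2% with it.

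The mfb1_aac2mut and aac2mut libraries show the deletion in cells with the clogging allele, where it came with many more changes. Here 1240 features were higher and 1167 lower, and 97 moved at least 2-fold. Ribosome biogenesis genes were lower in 89 of 100 cases and higher in 0 (95 and 0 adjusted over the list alone, median -0.61, adjusted p = 4.58e-25, adjusted p = 0.339 with an estimated correlation), with NOP1 at -0.83 ± 0.08 and the pseudouridine synthase CBF5 at -0.73 ± 0.08. Cytosolic ribosome genes were lower in 111 of 132 cases and higher in 0 (123 and 0 adjusted over the list alone, median -0.37, adjusted p = 2.93e-22, adjusted p = 0.413 with an estimated correlation). Targets of Msn2 and Msn4 were higher in 34 of 44 cases and lower in 0 (37 and 0 adjusted over the list alone, median 0.57, adjusted p = 1.93e-15, adjusted p = 0.0637 with an estimated correlation), with HSP26 at 1.74 ± 0.12 and SOL4 at 1.33 ± 0.10. The membrane heat shock gene HSP30 was higher by 1.18 ± 0.09. Of the Hsp31 family and methylglyoxal enzymes, 10 of 11 were higher and 0 lower (11 and 0 adjusted over the list alone, median 0.56, adjusted p = 8.74e-07, adjusted p = 0.088 with an estimated correlation), with HSP31 at 0.98 ± 0.11 and GLO1 at 0.56 ± 0.06.

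Oxidative stress genes were higher in mfb1_aac2mut than in aac2mut in 24 of 39 cases and lower in 1 (25 and 1 adjusted over the list alone, median 0.28, adjusted p = 2.04e-07, adjusted p = 0.0529 with an estimated correlation), and autophagy genes in 19 of 33, with 0 lower (21 and 0 adjusted over the list alone, median 0.28, adjusted p = 8.74e-07, adjusted p = 0.16 with an estimated correlation). ATG14 rose by 1.06 ± 0.11 and ATG8, the ubiquitin-like protein of the autophagosome, by 0.73 ± 0.08. Phosphate genes under Pho4 were lower in 12 of 21 cases and higher in 1 (13 and 1 adjusted over the list alone, median -0.41, adjusted p = 1.7e-05, adjusted p = 0.088 with an estimated correlation), with PHO84 at -1.65 ± 0.13 and GIT1 at -1.49 ± 0.13. PET9 was lower by 0.60 on the log2 scale (SE 0.06, adjusted p = 3.62e-05). Of the 16 largest changes, 14 were MFB1, mating-type genes or their neighbours, led by the same genes as in mfb1 against WT, with AGA2 at 4.60 ± 0.24, STE3 at -5.28 ± 0.09 and STE2 at 3.87 ± 0.09. The mating-type lists were the only 2 of 18 called lists that kept their call with an estimated correlation (adjusted p = 0.0141 and adjusted p = 0.0162). The other 2 were YLR154W-E (2.70 ± 0.62), among the ribosomal DNA repeats, and the small nuclear RNA form snR7-L (2.20 ± 0.41), both uncertain, and YLR154W-E was not called with the share of ribosomal RNA features as a covariate (adjusted p = 0.192). The share of ribosomal RNA features was 1.32 ± 0.10% in aac2mut and 3.53 ± 1.26% in mfb1_aac2mut, and with it as a covariate, chosen after seeing the data, 965 features were called in place of 2407. The effects of the deletion without and with the clogging allele had an r of 0.67 and a rho of 0.34 across genes, and an r of 0.38 and a rho of 0.33 without 43 mating-type genes and neighbours.

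**Figure D3:**
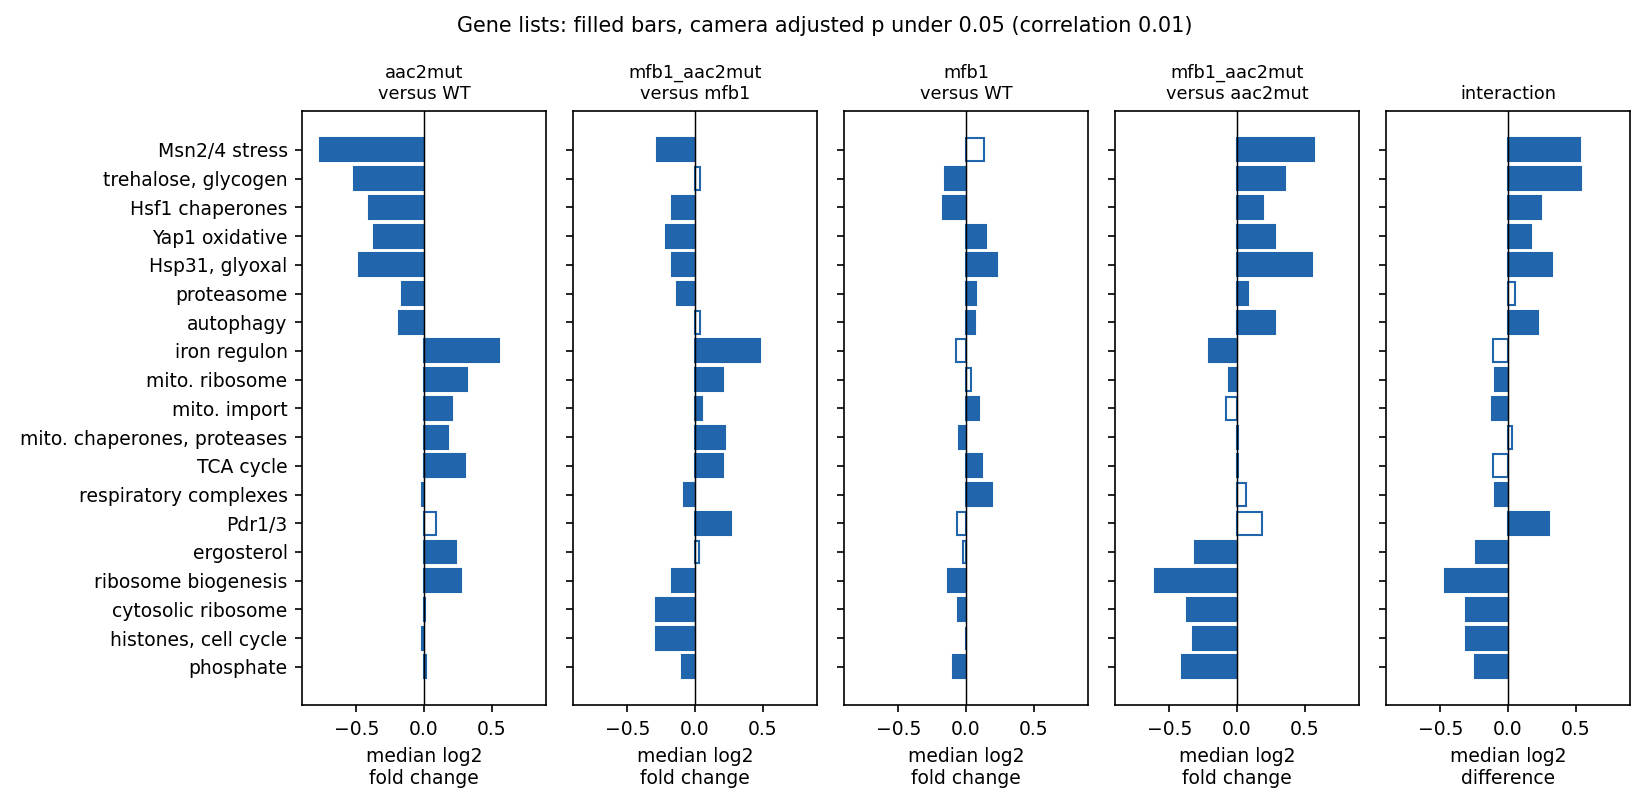
Bars give the median log2 fold change of each gene list in each comparison, or the median difference of the clogging effects in the interaction. Filled bars have a camera adjusted p under 0.05 with the preset correlation of 0.01. The Msn2/4 stress list has a median of -0.77 in aac2mut against WT and 0.57 in mfb1_aac2mut against aac2mut.

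The medians of the chromosomes stayed near 0 in the comparisons of aac2mut and mfb1 with WT, where the largest were -0.04 (chromosome IX) and 0.03 (chromosome VI). Genes of chromosome V were higher in mfb1_aac2mut. Their median was 0.19 against mfb1 and 0.18 against aac2mut over 283 tested genes, and the next largest chromosome medians were 0.04 and 0.06 in size. Each of the 3 mfb1_aac2mut libraries showed it, with medians of 0.22, 0.19 and 0.18 above the WT mean, whereas the other 9 libraries lay between -0.005 and 0.041. The interaction median of chromosome V was 0.14. Without chromosome V, an alternative chosen after seeing the data, 569 features were called in the interaction.

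**Figure D4:**
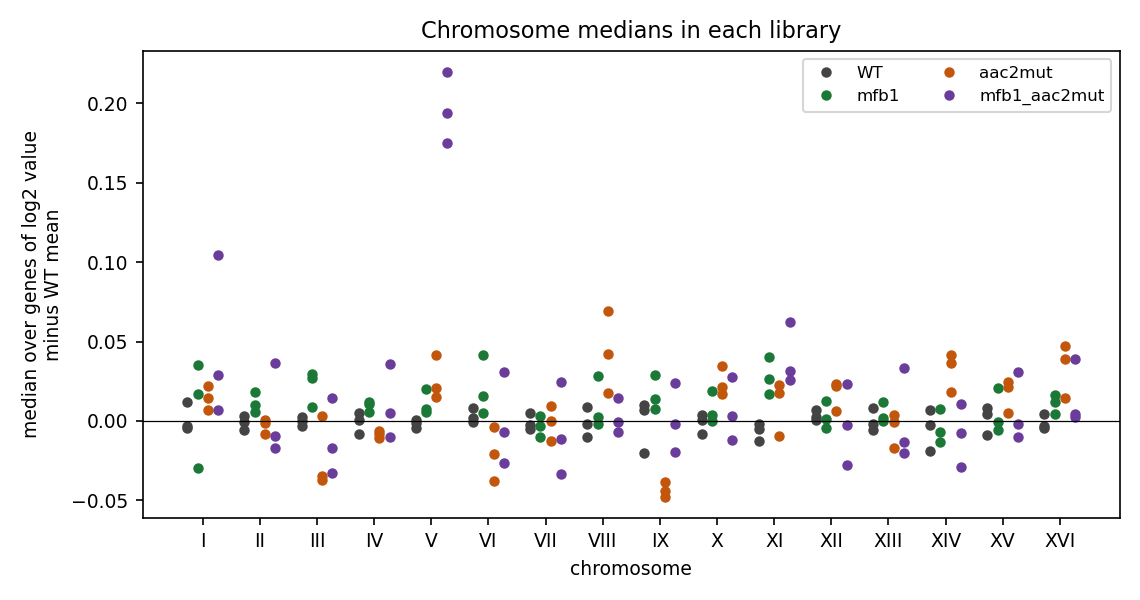
Each point is the median over the tested genes of a chromosome, in a library, of the log2 value minus the WT mean (y axis), by chromosome (x axis) and group. The 3 mfb1_aac2mut libraries stand at 0.18 to 0.22 on chromosome V, above all other points.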

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

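The tests of the mating-type split, of an extra chromosome V and its evenness, of the ribosomal RNA share, of the genes of chromosome V and of growth state were chosen after the results were seen; those of chance for chromosome V and of other splits of the libraries were planned.

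The effect of the clogging allele differed between cells with and without MFB1 by the interaction term for 639 features. Of these, 463 were also called with MFB1 and 306 without it, 318 only with MFB1, 161 only without it, and 56 were called in both with opposite signs. Of those called with MFB1, 181 had an effect of the same sign and smaller size without it. The rise of PET9 differed by -0.48 and the fall of HSP31 by 0.87. The largest positive values were those of SSA4 (1.57), HSP30 (1.36), HXT13 (1.96), the small nuclear RNA form snR7-L (2.86) and the ribosomal RNA spacers ITS2-1 (1.83), ITS2-2 (1.68), ITS1-1 (1.37) and ITS1-2 (1.36), which lie in repeats and are uncertain. The largest negative values were those of YHP1 (-1.55), YOX1 (-1.54), PHO84 (-1.45), YCL041C (-1.30), YLR042C (-1.28), ECM13 (-1.28), SPG3 (-1.21) and PCL1 (-1.18). HXT13 was not called without WT replicate 3 (adjusted p = 0.0506), and YCL041C was not called without WT replicate 3 or aac2mut replicate 3 (adjusted p up to 0.0611). YLR042C was not called without WT replicate 1, WT replicate 3, mfb1 replicate 2, mfb1 replicate 3, aac2mut replicate 3 or mfb1_aac2mut replicate 1 (adjusted p up to 0.0616), and SPG3 was not called in 10 of the 12 fits that leave out a library, all but those without WT replicate 2 or mfb1_aac2mut replicate 1 (adjusted p up to 0.109). With the ribosomal RNA share as a covariate, chosen after seeing the data, YLR042C (-1.26, adjusted p = 0.0547) and SPG3 (-1.16, adjusted p = 0.0936) were not called, and the other 14 of these 16 genes were.

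Among genes of the lists, the interaction was positive for HSP26 (1.29), HSP42 (0.85), SSE2 (0.97), SOL4 (0.90), OYE3 (1.15), OYE2 (0.80), PIG2 (0.78), GLC3 (0.90), TPS1 (0.55) and ATG14 (0.75). It was negative for NOP1 (-0.71), TIF6 (-0.55), ALB1 (-0.88), UTP15 (-0.90), RPS27A (-0.84), CLN1 (-0.70), FET3 (-0.67), GAS1 (-0.56) and GIT1 (-0.96). The called lists with a positive median were Msn2/4 targets (0.53), trehalose and glycogen (0.54), the Hsp31 family and methylglyoxal enzymes (0.32), the drug resistance list built around Pdr1 and Pdr3 (0.30), Hsf1-linked chaperones (0.24), autophagy (0.22) and oxidative stress (0.17). Those with a negative median were ribosome biogenesis (-0.47), the cytosolic ribosome (-0.31), histones and cell cycle (-0.31), phosphate (-0.24), ergosterol (-0.24), cell wall (-0.16), import machinery (-0.12), respiratory complexes (-0.10) and the mitochondrial ribosome (-0.10). With an estimated correlation 0 of these lists were called. Some of them held few called genes, against 639 of 6044 features in all. The drug resistance list had 1 of 26, positive, and the mitochondrial ribosome 1 of 75, negative. Import machinery had 3 of 42, all negative (0 adjusted over the list alone). The respiratory complexes had 2 positive and 1 negative of 44, so their medians do not mark single genes.

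The first pattern weighed is the interaction of stress and ribosome genes. With the ribosomal RNA share as a covariate the median of the Msn2/4 targets was 0.57 (camera adjusted p = 2.95e-16 at the preset correlation), against 0.53 without it. The median was not reduced, so a linear effect of the share, as seen within groups, did not account for it. That slope rests on differences within groups, which were small in WT (SD 0.27%) and aac2mut (SD 0.10%). The share also differed between the groups, so the fit cannot fully separate it from the genotypes. Without the covariate the list was not called with an estimated correlation (camera adjusted p = 0.227), and that test was not run with the covariate. Of 100 splits of the 12 libraries, 3 gave as many genes, the real one included, and the highest of the other splits gave 1222 against the real 639. Splits that mix the groups carry the main effects, a structure of the samples, so they are not a reference free of change and do not settle whether chance can be excluded. What stays open as well is the higher level of chromosome V genes, since 0 of the mfb1_aac2mut libraries lack it and an effect on genes elsewhere cannot be told apart from the loss of MFB1 in this group. Also open is the growth state of the cultures, for which no density per library is given. The median of the Msn2/4 targets less that of ribosome biogenesis was 3.29 ± 0.19 in WT, 3.56 ± 0.13 in mfb1, 2.22 ± 0.16 in aac2mut and 3.37 ± 0.25 in mfb1_aac2mut (SD, n = 3), with a widest spread within a group of 0.501. A difference in growth state and the loss of MFB1 cannot be told apart here, since each strain has its own cultures. The biological explanation, a loss of MFB1 that alters the response to import clogging, stays open. It is confounded with mating type as read from expression, and the clogging allele itself with the loss of LYS2 expression. PET9 also stood lower in mfb1_aac2mut (15.89) than in aac2mut (16.50), in counts of both alleles. Whether the level of the clogging allele differed was not tested, so a difference in it stays open as well.

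The second pattern is the mating-type split. MFB1 values were against the label in 0 of the 12 libraries, which argues against wrong genotype labels. The median MATα gene stood at 4.13% of its WT level at most in a deletion library. Single genes kept different shares, 61.5% for MATALPHA2 and 59.6% for HMLALPHA2, which share sequence with the silent copies and HMRA2, 12.5% for SAG1, 9.07% for AFB1, 3.34% for STE3, 0.483% for MF(ALPHA)1, 0.170% for MF(ALPHA)2 and 0.0151% for MATALPHA1. A share of MATα cells would leave each gene at that share at least, so MATALPHA1 and MF(ALPHA)2 argue against all but a very small one, and the bound of 5% was set after the values were seen. Haploid-specific genes had a median of -0.0311 in mfb1 against WT, whereas in diploid cells with both mating types they would fall. In mfb1_aac2mut against aac2mut 7 of the 19 were lower and 2 higher, with a median of -0.12 and FAR1 at -1.55, SST2 at -0.87 and STE12 at -0.71, so the test bears on the mfb1 libraries. The deletion libraries may come from MATa cells, a hypothesis found and tested on the same data, and cells with more than 1 MATa copy were not tested. With 0 deletion libraries of the WT mating type, the loss of MFB1 and the mating type cannot be told apart as sources of the other changes. The strain labels name W303-1B for all 12 libraries.

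The third pattern is the rise of chromosome V genes in mfb1_aac2mut, by a median of 0.19 against mfb1, with 208 of 283 genes (73.5%) higher. The highest median among 10000 random gene sets matched on expression was 0.062, which argues against a chance draw of genes. The sets were drawn gene by gene from the same fitted changes. They allow neither for linked neighbours, nor for the spread between libraries, nor for the choice of the chromosome with the largest median. The upper 95% bootstrap bound was 0.224, far from the shift of a second copy in every cell. The chromosome was divided by gene order into 5 parts of like size, with medians of 0.213, 0.112, 0.166, 0.106 and 0.288. All lay over a bound of 0.1 set after the values were seen, but a whole extra copy would shift the parts alike, and 3.77% of 10000 shuffles of the gene order gave as wide a range (0.182). An extra copy of chromosome V in part of the cells thus stays open as a possible explanation, neither excluded nor borne out. For a median fold of 1.14 it would need 1 extra copy in 13.7% of cells. No DNA was measured, and a biological cause was not tested.

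For the 4 pairwise comparisons the 10 splits of 6 libraries are too few for a share under 0.05. The real split gave 2490 genes for aac2mut against WT, 400 for mfb1 against WT, 2407 for mfb1_aac2mut against aac2mut and 2065 for mfb1_aac2mut against mfb1, each with 1 split as large, the real one, and a highest other of 0.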

How the results depend on the processing

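The tests without mating-type genes, without chromosome V, on protein-coding genes only and with the ribosomal RNA share as a covariate were chosen after the data were seen. Among the named genes and the called lists, the alternatives kept every called direction except 1. The other called features were counted but not compared in direction. For the largest rises and falls, leaving out a library could not reverse the sign, since no overlap between the libraries was required of them. Limma without trend, robust empirical Bayes and the limit of 2-fold leave the fold changes as they were. The list of the cytosolic ribosome in mfb1 against WT, with a median of -0.06, ranged from -0.146 (without mfb1 replicate 3) to 0.0188 (without mfb1 replicate 1) when each library was left out, and the cause was not tested. Over all alternatives, values of named genes stayed on their side of the threshold 15380 times, lost a call 1153 times and gained one 1 time. Called lists kept their call 2346 times, lost it 89 times and reversed 1 time under the alternatives other than the estimated correlation. With that correlation 6 of the 91 called lists kept their call.

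A limit of 2-fold left 145 genes for aac2mut against WT, 30 for mfb1 against WT, 97 for mfb1_aac2mut against aac2mut, 108 for mfb1_aac2mut against mfb1 and 50 in the interaction, by its construction. With the ribosomal RNA share as a covariate the counts were 148 for mfb1 against WT, 965 for mfb1_aac2mut against aac2mut and 372 in the interaction, and with only the libraries compared 260 for mfb1 against WT. The cause was not tested. Leaving out each library in turn gave 1855 to 2524 genes for aac2mut against WT, 163 to 482 for mfb1 against WT, 1821 to 2498 for mfb1_aac2mut against aac2mut, 1474 to 2199 for mfb1_aac2mut against mfb1 and 200 to 966 in the interaction. Of the genes called in mfb1 against WT 58.3% were higher, but 39.2% with the covariate, 48.1% with only the libraries compared, 42.9% without WT replicate 1 and 39.3% without mfb1 replicate 1.

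With an estimated correlation camera called 1 list for aac2mut against WT, 2 for mfb1 against WT, 2 for mfb1_aac2mut against aac2mut, 1 for mfb1_aac2mut against mfb1 and 0 in the interaction, in place of 17, 19, 18, 21 and 16. Leaving out each library gave 17 to 19, 14 to 19, 16 to 19, 17 to 22 and 15 to 19. The correlation of the clogging effects was 0.508 to 0.594 without each library, and that of the deletion effects 0.591 to 0.699, 0.786 over genes past the threshold and 0.381 without mating-type genes. The median of chromosome V was 0.165 against mfb1 over genes with a mean of 50 or more. Without each library it was 0.158 to 0.180 against aac2mut, 0.167 to 0.197 against mfb1 and 0.128 to 0.155 in the interaction.

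The correlations showed no pairing by replicate number, as 3 of 12 libraries correlated best on average with libraries of their own number. Between libraries of the same number r ran from -0.34 to 0.29. A batch shared by number is not excluded by this. With the number as a block the counts were 2575, 433, 2523, 2153 and 832 in the order above. Quantile normalization moved next to nothing, as the values already have it. Count models on whole reads were not run, since the reads cannot be recovered. Depth is unknown, so no limit from it is given.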

Other observations

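The families in this part were chosen after the results were seen, and no test of a hypothesis was run on them.

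Of 16 hexose transporter genes, 9 were called higher and 3 lower in aac2mut against WT, and 8 higher and 0 lower in mfb1_aac2mut against mfb1. HXT5 rose by 1.09 in aac2mut against WT and 1.18 in mfb1_aac2mut against mfb1, HXT6 by 0.55 and 0.59, and HXT7 by 0.45 and 0.53. The 3 lower in aac2mut against WT were HXT13 (-2.02), HXT10 (-0.79) and HXT9 (-0.56). HXT3 rose by 0.30 in aac2mut against WT and was measured at -0.03 in mfb1_aac2mut against mfb1 (adjusted p = 0.779). HXT6 and HXT7 are near-identical, as are HXT15 and HXT16, and their values are uncertain.

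The pyridoxine genes SNZ1 and SNO1 rose by 1.45 and 1.56 in aac2mut against WT and by 1.32 and 1.54 in mfb1_aac2mut against mfb1. SNZ2 and SNZ3, near-identical to each other, changed by -0.29 and -0.35 in aac2mut against WT. Of 7 genes known from cells short of oxygen, 4 were called lower in aac2mut than in WT, ANB1 (-2.57), HEM13 (-0.48), CYC7 (-0.81) and COX5B (-0.96), and 1, OLE1, was called higher (0.87). AAC3 (-0.79, adjusted p = 0.0681) and TIR1 (-0.05, adjusted p = 0.88) were not called. In mfb1_aac2mut against mfb1, 4 were called lower, ANB1 (-1.92), HEM13 (-0.47), COX5B (-0.34) and TIR1 (-0.91), and 0 higher, and CYC7 was measured at -0.04 (adjusted p = 0.782).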
